A study of Danio rerio with 6 samples.

How the data were processed

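Whole zebrafish embryos were kept in water, 1% ethanol or 1.5% ethanol from 4 h to 24 h after fertilisation, per the labels, and collected at 24 h. MicroRNA (miRNA) was measured on 6 one-colour arrays, 2 biological replicates in each of the 3 groups. Each array held 24 printed blocks and 5040 spots. Of these, 972 spots carried 243 probes named for zebrafish miRNAs, 4 spots per probe. Another 3340 spots carried probes named for miRNAs of other species, 336 spots were empty, 40 were blank and 8 were named Ncode_Control. Of the zebrafish probes, 218 carried registered zebrafish names and 25 carried names beginning ZF_miR, whose meaning is not given in the sources used here. Probe names follow an older nomenclature, closely related family members can share signal on such probes, and no genome position was used.

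The deposited scanner files hold, per the file headers, the raw foreground intensity and local background intensity of each spot in 1 channel, without background subtraction. The deposited value table is on a log2 scale. It was rebuilt from the scanner files as the mean log2 foreground of a probe's kept spots of intensity 100 or more, minus the mean log2 of the Ncode_Control spots of the same array. Of its 1440 values, 1438 were rebuilt to within 0.001, the largest difference was 0.137, and 18 values were missing from the table. The authors' log2 table was used as an alternative, not for the main values.

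For the main values, the raw intensities were corrected by the normexp method with an offset of 50, set on the log2 scale and quantile normalised over the miRNA spots of the 6 arrays. Spots with the ignore mark of the quantification software, 4.64% to 11.7% of the spots of an array, were left out after the background correction and before the normalisation. The remaining spots of a probe were averaged. R 4.3.3 and limma 3.58.1 were used. A spot counted as over its local background when its foreground was over that background by 2 SD. This filter left all 243 zebrafish probes in the test on these arrays, but it did not separate signal from empty spots, since 83.6% to 94.4% of empty and blank spots also passed it. A second measure was therefore added after the data were seen: a probe was called above the empty spots on an array when as many of its kept spots as not, or more, lay over the 95th percentile of the empty and blank spots of that array.

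A linear model with the 3 groups was fitted to all 6 arrays with limma, with moderated variances, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over the 243 probes, with a threshold of 0.05. The model had 3 residual degrees of freedom and a prior of 3.15. The comparisons were 1% ethanol with control, 1.5% ethanol with control, 1.5% with 1% ethanol, both doses together with control, and any difference among the groups (moderated F test). An exact test of 2 arrays against 2 cannot give a two-sided p under 0.333, so single probes rest on the model. The number of arrays limits the precision: the median standard error (SE) of a log2 fold change was 0.21. Tested on simulated data in which 60 of the 243 probes changed, the model found 72.1% of changes of 1 log2 unit, and 3.99% of its calls were false. With 4 changed probes it found 28.0% of changes of 1 log2 unit and 68.5% of changes of 2. In 20 simulated runs without change it made 2 calls. The simulated changes were added in full to normalised values, without a background floor or saturation. The rates therefore do not apply to falls of the 159 probes above the empty spots on no array.

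The log2 fold changes of both doses were compared across probes by Pearson's r, beside 1000 simulations in which no probe changed and both doses shared the same control arrays. Lists of miRNAs were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over lists. The 18 lists were the miR-430 family, the let-7 family, neural, sensory, muscle and heart, blood and immune, endothelial, epithelial and skin, gut, liver and pancreas, Hox cluster, cartilage and mesenchyme, miR-17-92 clusters, miR-125/100/99 clusters, miR-30 family, miR-29 family, miR-23/27/24 cluster, ethanol-responsive in rodents, and late-onset in zebrafish. The miR-29 family had 2 probes, under the 3 needed, so 17 lists were tested. Many members are expressed in several tissues of the embryo and some stand in more than 1 list.

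The miRNAs named were set by rule. For a comparison with control with fewer than 10 past the threshold, they were the 10 with the smallest p in each direction, given as values and not as changes; for 1.5% with 1% ethanol they were the 5 in each direction. For each list they were the 3 members with the highest mean level, and the miR-430, miR-9, miR-153, let-7 and miR-34 families were always counted. The groups, the model, the lists, the naming rule and the first set of alternatives were fixed before the data were examined. Those alternatives were no background subtraction, a normexp offset of 10, median scaling, no normalisation, cyclic loess, no filter, detection on all 6 arrays, the median over spots, the authors' table, trended and robust moderation, array weights, only the groups compared, a replicate block, a slide block, each array left out, and a threshold of 0.1. Added after the data were seen were scaling to empty and blank spots, to the Ncode_Control spots or to the 75th percentile, keeping ignored spots, limits to probes above the empty spots on both arrays of a group, on at least 1 array or on all 6, random slide and replicate effects, position on the slide, pairs of these, the neural list without miR-128, and the correlation between doses without miR-736.

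Arrays whose files named the same experiment were taken to share a slide, and the spot coordinates to give the position on it. This is an inference, since slides are not given in the sources used here. It gave 3 slides of 2 arrays. Slide 1 held control replicate 1 and 1% ethanol replicate 1, slide 2 control replicate 2 and 1.5% ethanol replicate 1, and slide 3 the second replicates of both doses. On this reading slide and group are partly confounded, and differences within a slide are given beside the pooled ones for miR-128, miR-193b, miR-736, let-7c and miR-218a. Correlations of the replicate differences between groups were -0.03, 0.27 and -0.04, so the replicate numbers were not treated as pairs in the main model. Probes of other species were not part of the comparisons. The number-named spots and the spots named Homo were not used here, since their content is not given in the sources used here.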

Results

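MicroRNA was profiled in whole zebrafish embryos at 24 h after fertilisation, after growth in water, 1% ethanol or 1.5% ethanol from 4 h onwards. Each group had 2 arrays, from 2 biological replicates. The median foreground of zebrafish probe spots was 226 and 166 intensity units on the control arrays, 165 and 172 at 1% ethanol, and 184.5 and 169 at 1.5% ethanol. Empty and blank spots had medians of 127 and 101, 104 and 99, and 112 and 98 in the same order. Of the 243 zebrafish probes, 28 lay above the empty spots on all 6 arrays, 84 on at least 1, and 159 on none. Probes named for worm or insect miRNAs alone were above the empty spots at 12.6% to 18.1% per array, beside 14.4% to 23.05% of the zebrafish probes. Whether these probes share sequence with zebrafish miRNAs was not checked. Replicate arrays correlated across zebrafish probes at r = 0.951 in control, 0.924 at 1% and 0.953 at 1.5% ethanol, and probes are not independent replicates. Arrays of different groups correlated at 0.865 to 0.961, so this measure did not set replicates apart from arrays of other groups. No genome coordinates are given for the miRNAs.

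On both control arrays, signal above the empty spots was found for 2 of 5 probes of the miR-430 family, 6 of 25 neural, 1 of 8 muscle and heart, 1 of 4 epithelial and skin, 3 of 10 let-7 and 4 of 20 miR-17-92 probes. Worm and insect probes passed the same limit at 14.8% and 17.03% on these arrays, beside 20.2% and 17.28% of zebrafish probes, so passing it does not by itself show that a miRNA was expressed. Levels below are normalised log2 intensities, as mean ± SD (n = 2). In the miR-430 family, which clears maternal mRNA in the early embryo, miR-430j was at 10.90 ± 0.14 and miR-430b at 10.14 ± 0.12 in controls. Among neural miRNAs, miR-9 was at 13.20 ± 0.11, miR-132 at 13.60 ± 0.09, and miR-218a was saturated in all 4 spots on both control arrays. The muscle miRNA miR-1 was at 9.01 ± 0.04, the epidermal miR-203a at 13.91 ± 0.74, and miR-196b of the Hox clusters at 10.40 ± 0.08. Let-7e was at 11.21 ± 1.02, let-7b at 10.63 ± 0.15, and miR-19a of the miR-17-92 clusters at 12.38 ± 0.22. Further levels were 12.01 ± 0.30 for miR-146b, 9.68 ± 0.10 for miR-155, 11.68 ± 0.11 for miR-30e and 14.38 ± 0.05 for miR-23a. The brain-enriched miR-124 was at 7.51 ± 0.07 and above the empty spots on 1 array, and the liver miRNA miR-122, at 7.76 ± 0.14, and the endothelial miR-126, at 7.70 ± 0.51, on none.

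The first comparison asked which miRNAs differed in embryos raised in 1% ethanol. miR-128, a miRNA enriched in the nervous system, fell: it was at 8.85 ± 0.09 in control and 6.93 ± 0.11 at 1% ethanol (SD, n = 2), with both 1% arrays below both control arrays. The log2 fold change was -1.93 (SE 0.20, limma adjusted p = 0.0152). Because neither 1% array was above the empty spots, the size of the fall is not fixed. With the lowest probe mean above the empty spots on each 1% array as a floor, the fall was 1.98-fold. This is not a strict lower bound, since miR-192, above the empty spots on neither 1% array, averaged 8.10 there, over that floor. Let-7c, of a family tied to developmental timing, was at 8.62 ± 0.23 and 6.95 ± 0.32, a log2 fold change of -1.67 (SE 0.39, adjusted p = 0.498), which did not pass over all probes. Of the alternatives added later, it passed when scaled to empty and blank spots (-1.84, adjusted p = 0.0437), and with position on the slide as a block on the 84 probes above the empty spots on at least 1 array (-1.67, adjusted p = 0.0176). It was likewise above the empty spots on both control arrays and neither 1% array. The same floor gave a 1.69-fold fall, again not a strict bound, and not past the threshold over all probes.

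In all, 1 of 243 miRNAs passed at 1% ethanol, with 0 higher and 1 lower. At an unadjusted p under 0.05 there were 15, of which 5 were higher and 10 lower, where 12.15 are expected by chance. Larger but scattered differences came from miR-193b, at 13.44 ± 0.74 in control and 9.82 ± 2.01 at 1% (adjusted p = 0.498), and miR-736, at 10.47 ± 2.39 and 7.68 ± 1.06 (adjusted p = 0.676). On the second 1% array the 4 spots of miR-193b ranged from 638 to 8428, and those of miR-736 reached at most 1289 on the second control array, against at least 6215 on the first. Within slide 1, with slides inferred from the scanner files, the 1% minus control difference was -5.57 for miR-193b and -5.23 for miR-736, beside -1.73 for let-7c and -1.67 for miR-218a. None of these sizes is fixed. The 1% array was not above the empty spots for miR-193b, miR-736 or let-7c, and the control was saturated for miR-218a. With slide as a block miR-193b (-4.12) and miR-736 (-3.72) passed along with miR-128, all 3 with the same SE of 0.43. They did not when limited to the 84 probes above the empty spots on at least 1 array, where the SE of miR-193b and miR-736 was 1.02 and 1.06 (adjusted p = 0.507 and 0.557). On the same 84 probes with position on the slide as a block, miR-193b and miR-736 passed, along with miR-128 and let-7c. Under the 75th percentile scaling miR-193b (-3.32) and miR-736 (-2.60) passed too, each with an SE of 0.52. Both probes sat in 1 pair of print blocks where 6 of 8 compared probes were low on 1% ethanol replicate 1. The other named lower miRNAs were miR-214 (-0.58), miR-146a (-0.77), miR-140 (-0.71), miR-144 (-0.50), miR-23a (-0.98) and miR-129 (-0.57), as log2 fold changes with adjusted p from 0.676 to 0.755. The 10 named higher ones were ZF_miR_22 (0.59), miR-216a (0.57), ZF_miR_15 (0.51), miR-454a (0.66), miR-725 (0.87), miR-30d (0.36), let-7j (0.46), miR-19a* (0.39), miR-145 (0.44) and miR-133a (0.35), with adjusted p from 0.676 to 0.874. Of these 10, 8 were above the empty spots on no array. Probes whose 1% arrays both lay above both controls numbered 50, and 41 had both below, where chance gives 40.5 each way (16.7%). For miR-218a, saturated in control, the mean at 1% ethanol was 1.99-fold lower, a size that saturation may understate, and not past the threshold (limma adjusted p = 0.755). Its spots read 20161 to 26618 on the first 1% array and 48456 to 52292 on the second.

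Within slide 1 the 1% minus control difference of miR-128 was -2.07, a size not fixed, since the 1% array was not above the empty spots. With slide as a block, in a model with 1 residual degree of freedom, its log2 fold change was -1.83 (adjusted p = 0.00275). Its SE rose from 0.20 to 0.43, the same SE as for miR-193b and miR-736. That p thus uses a spread shared by probes and is no measure of how miR-128 itself varied. With the replicate block the log2 fold change of miR-128 was -1.93 (adjusted p = 0.0267). Limited to the 84 probes above the empty spots on at least 1 array, the call ended with the slide block (-1.83, SE 0.37, adjusted p = 0.466) and with the replicate block (-1.93, SE 0.23, 0.0696). The call also ended without control replicate 1 (adjusted p = 0.311), control replicate 2 (0.190) or 1% ethanol replicate 1 (0.0774), and without 1% ethanol replicate 2 there were 3 calls, miR-128, miR-193b and miR-218a. It ended, too, under the Ncode_Control scaling (-1.56, adjusted p = 0.108), the 75th percentile scaling (-1.52, 0.289), no normalisation (-1.81, 0.0531), the authors' table (-1.59, 0.116) and the median over spots (-1.98, 0.174), within a range of 0.00249 to 0.466 over 37 alternatives, 26 of which kept it.

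**Figure D1:**
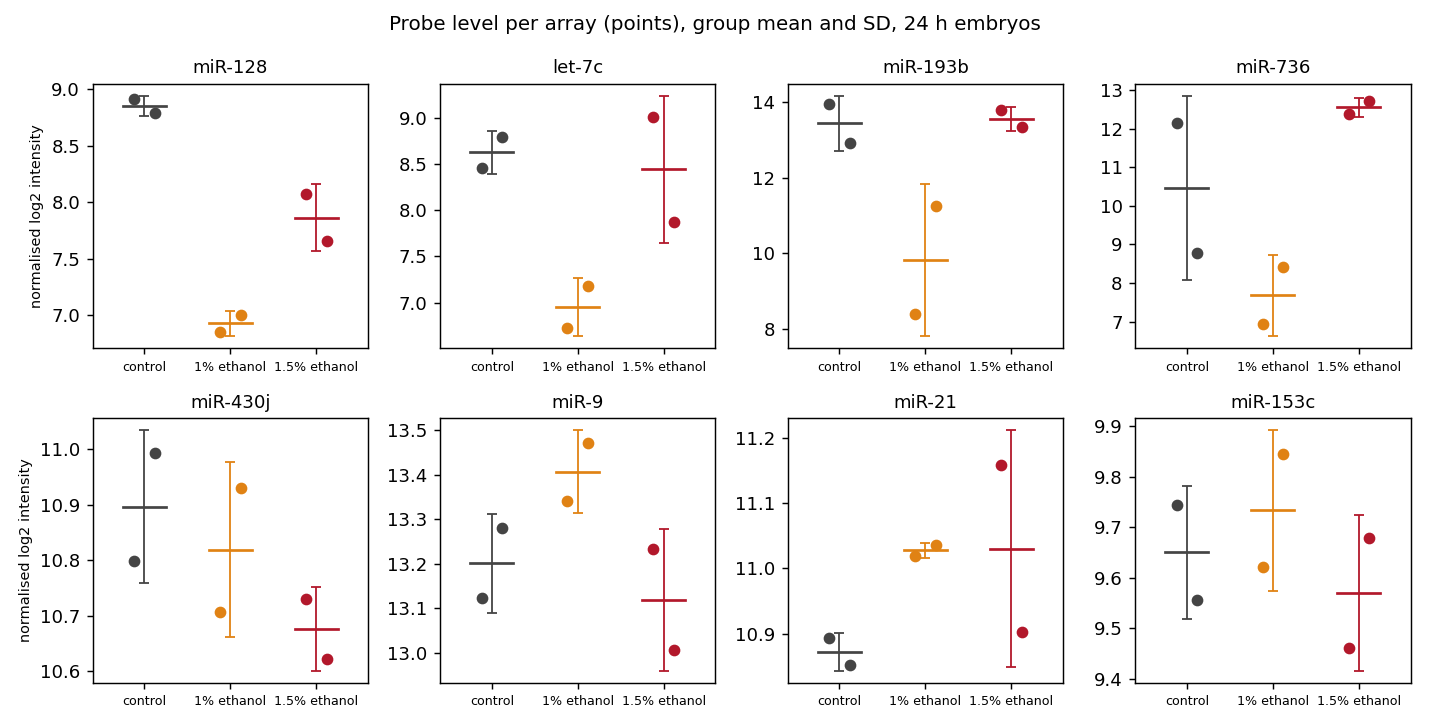
Normalised log2 intensity of 8 miRNA probes on each of the 6 arrays (points), with the group mean (line) and SD (bar, n = 2), for control, 1% ethanol and 1.5% ethanol; each panel has its own axis, which does not start at 0. miR-128 averaged 8.85 in control, 6.93 at 1% and 7.86 at 1.5% ethanol, and miR-193b and miR-736 differed widely between replicates.

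By tissue group, camera passed 0 of 17 lists at 1% ethanol (lowest adjusted p = 0.958, 0 lists at an unadjusted p under 0.05). With an estimated correlation it also passed 0 (lowest adjusted p = 0.965), as did the directional fry test. Some lists could hardly show a shift. Above the empty spots on any array were 0 of 4 endothelial, 1 of 7 cartilage and mesenchyme, 1 of 6 miR-30, 1 of 5 miR-125/100/99 and 2 of 11 sensory probes. The numbers were 9 of 25 for neural, 4 of 8 for muscle and heart, and 3 of 5 for miR-430 probes. In the neural list, 1 of 25 members fell, miR-128, and 24 did not pass; adjusted over the list alone it was also 1 (adjusted p = 0.00156). Of the others, miR-132 had a log2 fold change of -0.31 and miR-9 of 0.21. In the let-7 family, 0 of 10 passed over all probes and 1, let-7c, adjusted over the list alone (adjusted p = 0.0481), while let-7e was at 11.78 ± 0.27 and let-7b at 10.44 ± 0.20 in 1% ethanol. The blood and immune list had 0 of 10 past, with miR-146b at 0.36, miR-155 at 0.14 and miR-146a at -0.77. Muscle and heart miRNAs gave 0 of 8, with miR-1 at 0.29, miR-133a at 0.35 and miR-499 at 0.00. In cartilage and mesenchyme, where miR-140 is a cartilage miRNA, 0 of 7 passed, with miR-199* at 0.35, miR-143 at 0.15 and miR-145 at 0.44. Epithelial and skin had 0 of 4, with miR-203a at -1.48, miR-205 at -0.03 and miR-203b at 0.00. The miR-23/27/24 cluster had 0 of 9, with miR-23a at -0.98 and miR-27c* at 0.27.

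Lists defined by stage, cluster or other organs held no further call at 1% ethanol, over all probes or adjusted over the list alone. The miR-430 family had 0 of 5, with miR-430j at -0.08, miR-430b at -0.25 and miR-430a at 0.10. For the ethanol-responsive list drawn from rodent work, 0 of 16 passed, with miR-9 at 0.21, miR-21 at 0.16 and miR-153c at 0.08. The late-onset list had 0 of 31. Among sensory miRNAs 0 of 11 passed, with miR-96 at 0.19, miR-200a at 0.24 and miR-184 at 0.02. Gut, liver and pancreas had 0 of 8, with miR-192 at -0.26, miR-375 at -0.06 and miR-122 at 0.03. The endothelial list had 0 of 4, with miR-126 at -0.20, miR-222 at 0.22 and miR-126* at -0.26. The Hox cluster list had 0 of 8, with miR-196b at -0.19, miR-10a* at 0.15 and miR-10c at 0.32. Of the miR-17-92 clusters 0 of 20 passed, with miR-19a at 0.23, miR-92b at -0.09 and miR-18b* at 0.12. The miR-125/100/99 clusters had 0 of 5, with miR-100 at 0.40, miR-125a at 0.28 and miR-125c at 0.18. The miR-30 family had 0 of 6, with miR-30e at -0.28, miR-30a at 0.06 and miR-30c at 0.03. The miR-29 family, too small to test, had miR-29b at -0.22 and miR-29a at 0.02.

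List medians at 1% ethanol ran from -0.17 (let-7 family) to 0.18 (miR-125/100/99 clusters), on the log2 scale. Relative to the median of all probes, 3 of 17 list medians turned sign under no normalisation, cyclic loess or the Ncode_Control scaling: those of the miR-430 family, the neural list and the ethanol-responsive list. Scaling by 1 constant per array cancels in these values. The median and the camera direction differed in sign for the miR-430 family, neural, muscle and heart, endothelial and miR-30 lists, and the miR-430 family, Hox cluster and neural lists had a mean below 0 with a median above it. The mixed fry test, which asks whether members differ in either direction, passed for the neural list (adjusted p = 0.0190) and for cartilage and mesenchyme (adjusted p = 0.00387). Of the cartilage and mesenchyme probes, 1 of 7 was above the empty spots on any array, so that call rests mostly on probes near background. The neural result was not past without miR-128 (adjusted p = 0.649), and with slide as a block neither passed (both adjusted p = 0.766). With each array left out, adjusted p ran from 0.0490 to 0.283 for the neural list and from 0.104 to 0.735 for cartilage and mesenchyme. With the replicate block cartilage and mesenchyme passed (adjusted p = 0.0464), as did the miR-23/27/24 cluster, and the neural list did not (0.103); without control replicate 2 the endothelial list alone passed.

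The second comparison asked the same of 1.5% ethanol. No miRNA passed: miR-128 was at 7.86 ± 0.30 (SD, n = 2), beside 8.85 ± 0.09 in control, a log2 fold change of -0.99 (SE 0.20, limma adjusted p = 0.380), with both 1.5% arrays below both controls and 1 of them above the empty spots. The probe ZF_miR_9 was at 8.15 ± 0.06 beside 7.37 ± 0.13, a log2 fold change of 0.77 (SE 0.16, adjusted p = 0.380). miR-724 was at 8.60 ± 0.36 beside 9.25 ± 0.24 (-0.65, adjusted p = 0.941). Levels of miR-9 (13.12 ± 0.16), miR-430j (10.68 ± 0.08), miR-21 (11.03 ± 0.18) and miR-153c (9.57 ± 0.15) were each within 0.3 log2 units of control, with none past the threshold.

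With limma, 0 of 243 passed at 1.5% ethanol (lowest adjusted p = 0.380), beside 12 at an unadjusted p under 0.05, of which 4 were higher and 8 lower and 12.15 are expected by chance. The remaining named lower miRNAs were miR-214 (-0.55), miR-499 (-0.46), miR-200b (-0.50), miR-146a (-0.72), miR-140 (-0.64), miR-30b (-0.48), miR-144 (-0.47) and ZF_miR_10 (-0.38), with adjusted p from 0.932 to 0.964. The remaining named higher ones were miR-30d (0.43), miR-183 (0.53), miR-10d* (0.42), miR-732 (0.35), miR-736 (2.08), miR-107 (0.32), miR-133a* (0.36), miR-139 (0.34) and miR-148 (0.47), with the same range. Non-overlapping probes numbered 28 higher and 42 lower, where chance gives 40.5 each way (16.7%). Within slide 2, the 1.5% minus control difference of miR-128 was -0.71, and with slide as a block its log2 fold change was -0.95 (adjusted p = 0.80). With slide as a block 2 other miRNAs passed, miR-726 and miR-736, in a model with 1 residual degree of freedom, and with 75th percentile scaling 2 passed, miR-736 and ZF_miR_20. Within slide 2 the difference was 3.60 for miR-736, 0.87 for miR-193b and 0.22 for let-7c.

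At 1.5% ethanol, too, camera passed 0 of 17 lists (lowest adjusted p = 0.239, 1 list at an unadjusted p under 0.05), and with an estimated correlation 0 (lowest adjusted p = 0.960). The mixed fry test passed 0 (lowest adjusted p = 0.118), and without 1.5% ethanol replicate 2 it passed the let-7 family. Adjusted over the list alone, 0 miRNAs passed in any list. The list with that unadjusted p was cartilage and mesenchyme, with 6 of 7 log2 fold changes below 0 and a median of -0.16; its members miR-140 (-0.64), miR-214 (-0.55), miR-199* (-0.02) and miR-143 (0.04) each missed the threshold. In the blood and immune list 7 of 10 values were below 0, with miR-146b at -0.24 and miR-155 at -0.09. Of the neural list 16 of 25 were below 0, with miR-132 at -0.33. For the let-7 family 6 of 10 were below 0, with let-7e at 0.84 and let-7b at -0.56. Medians ran from -0.25 (endothelial) to 0.17 (miR-125/100/99 clusters). Relative to all probes, 3 of 17 medians turned sign under the same 3 scalings, those of the miR-430 family, the Hox cluster and the ethanol-responsive list. The mean was above 0 and the median below it for the miR-430 family and for epithelial and skin. Without 1.5% ethanol replicate 1, cartilage and mesenchyme was lower by camera (adjusted p = 0.0318), and without control replicate 1 the blood and immune list was (adjusted p = 0.0265). With an estimated correlation neither passed (adjusted p = 0.958 and 0.636).

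The doses were then compared with each other. None of the miRNAs differed past the threshold between 1.5% and 1% ethanol. The largest differences were in miR-736, at 12.56 ± 0.25 against 7.68 ± 1.06 (SD, n = 2; log2 fold change 4.88, SE 1.07, limma adjusted p = 0.291), and miR-193b, at 13.56 ± 0.32 against 9.82 ± 2.01 (3.74, SE 0.89, adjusted p = 0.320). miR-128 was 0.94 higher on the log2 scale at 1.5% (SE 0.20, adjusted p = 0.291), and within slide 3 that difference was 0.65; only 1 of these 4 arrays was above the empty spots for it, so the size of the difference is not fixed. Let-7c was at 8.44 ± 0.80 against 6.95 ± 0.32 (1.49, adjusted p = 0.404). With position on the slide as a block on the 84 probes above the empty spots on at least 1 array it passed (adjusted p = 0.0424). So did miR-193b, miR-736 and ZF_miR_20. Within slide 3 the difference was 4.30 for miR-736, 2.09 for miR-193b and 0.70 for let-7c, whose 1% array there was not above the empty spots.

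limma passed 0 of 243 between the doses, beside 18 at an unadjusted p under 0.05, 11 higher and 7 lower at 1.5%. The other named miRNAs were miR-210* (0.90), ZF_miR_22 (-0.85), miR-7b (-0.67), miR-200b (-0.57), miR-146b (-0.60) and miR-19a* (-0.55), with adjusted p from 0.291 to 0.509. Camera passed 0 of 17 lists (lowest adjusted p = 0.768, 0 at an unadjusted p under 0.05, and 0.908 with an estimated correlation), and 0 miRNAs passed adjusted over the list alone. Of the sensory probes, 2 of 11 were above the empty spots on any array, which limits the next result. The mixed fry test passed for the sensory list (adjusted p = 0.0341), whose members miR-183 and miR-200b were at 0.55 and -0.57; with slide as a block it did not (adjusted p = 0.805), and with each array left out it ran from 0.0479 to 0.176. Without 1.5% ethanol replicate 2 the mixed test passed 6 lists, the let-7 family, neural, sensory, Hox cluster, ethanol-responsive and late-onset, and without 1% ethanol replicate 1 the endothelial list alone. Medians ran from -0.20 (blood and immune) to 0.18 (epithelial and skin), and 5 of 17 turned sign relative to all probes under those 3 scalings: the let-7 family, sensory, muscle and heart, miR-30 family and ethanol-responsive lists. The median and the mean had opposite signs for the Hox cluster, muscle and heart, and late-onset lists. Without 1% ethanol replicate 2, 3 passed, miR-193b, miR-218a and ZF_miR_20. With slide as a block 4 passed, miR-193b, miR-203a, miR-736 and ZF_miR_20; 2 passed without normalisation, in the authors' table and under the Ncode_Control scaling, in each case miR-193b and miR-736.

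Taking both doses together against control, miR-128 fell, with a log2 fold change of -1.46 (limma adjusted p = 0.0331), and all 4 ethanol arrays lay below both controls. Because 3 of the 4 were not above the empty spots, the size of the fall is not fixed. The bound taken for it was 1.98-fold, which is not a strict lower bound. miR-128 was 1 of 243 miRNAs, with 0 higher, beside 8 at an unadjusted p under 0.05 (2 higher, 6 lower). It was also the only miRNA past the F test for any difference among the groups (adjusted p = 0.0480), beside 14 at an unadjusted p under 0.05. Camera passed 0 of 17 lists (lowest adjusted p = 0.816, 0 at an unadjusted p under 0.05, and 0.959 with an estimated correlation). Above the empty spots on any array were 1 of 7 cartilage and mesenchyme and 1 of 6 miR-30 probes. The mixed fry test passed for the neural, cartilage and mesenchyme, and miR-30 family lists, each at adjusted p = 0.0498. None of the 3 passed with slide as a block or with any array left out, where adjusted p ran from 0.0510 to 1.00, 0.112 to 0.896 and 0.112 to 1.00, and the neural list did not pass without miR-128 (adjusted p = 0.921). With the replicate block, both counts of miRNAs, for both doses and for any difference, were 0 (lowest adjusted p = 0.0551 and 0.0817). They were also 0 with median scaling (0.0859 and 0.122), cyclic loess (0.0715 and 0.110), no normalisation (0.187 and 0.0608), the median over spots (0.391 and 0.503), the authors' table (0.617 and 0.0602) and the Ncode_Control scaling (0.420 and 0.104). The F test alone gave 0 when limited to the 41 probes above the empty spots on both arrays of a group (0.0567) and with ignored spots kept (0.0715). The 75th percentile scaling gave 0 for both doses (0.177) and 3 by the F test, without miR-128, and slide as a block gave 2 and 6. With each array left out the count for both doses was 0 in every case (lowest adjusted p from 0.0524 to 0.559); the count for any difference was 0 in each case but 1, without 1% ethanol replicate 2, where miR-193b passed.

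Families followed for their place in development and in earlier ethanol work were counted separately. Of 5 miR-430, 2 miR-9, 3 miR-153, 10 let-7 and 3 miR-34 probes, 0 passed in any of the comparisons over all probes; adjusted over the list alone, let-7c passed at 1% ethanol. miR-34c, of a p53-responsive family, was at 9.64 ± 0.14 in control, 9.45 ± 0.11 at 1% and 9.44 ± 0.69 at 1.5% ethanol.

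Fold changes at both doses were set against each other across the 243 probes. Pearson's r was 0.04, beside 0.49 in simulations where no probe changed and the doses shared the controls (95% of simulations from 0.20 to 0.72), and Spearman's rho was 0.35 beside 0.46 (0.33 to 0.57). Without control replicate 1 or 2, r was 0.23 or 0.37, and without each ethanol array it ran from -0.08 to 0.18. The simulations used all 6 arrays, so their range is no reference for these values. With miR-736 left out, an alternative added later, r was 0.25 (simulated range 0.21 to 0.72) and the covariance 0.029 (0.019 to 0.108), both inside their ranges. The low values over all probes thus depended on that 1 probe. It was the probe whose removal raised r most, and the simulated ranges do not allow for that choice. Whether the other probes agree as simulated is therefore not shown. The covariance was 0.0053, or 0.052 below the simulated mean (0.021 to 0.116), and 61.7% of probes had the same sign beside 66.7% (60.9% to 72.0%). Among the 10 named lower miRNAs of each dose, 5 were shared, miR-128, miR-214, miR-146a, miR-140 and miR-144, and among the higher ones 1, miR-30d. Independent lists would share 0.41, but the shared controls add to such overlap, by an amount that was not simulated. The overlap is therefore no measure of a shared response. miR-214, miR-140, miR-144 and miR-30d were above the empty spots on no array, and miR-146a on 1. Of the shared miRNAs, 1 passed the threshold at 1% ethanol and 0 at 1.5%.

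**Figure D2:**
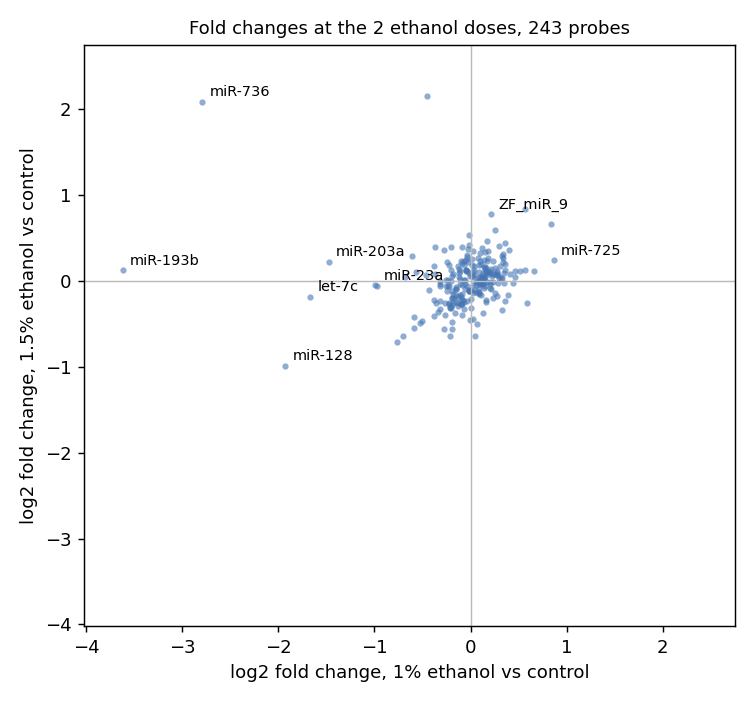
Log2 fold change against control at 1% ethanol (horizontal axis) and 1.5% ethanol (vertical axis) for each of the 243 zebrafish probes (points), with some named. miR-128 lies below 0 on both axes (-1.93 and -0.99), while miR-193b (-3.62 and 0.12) and miR-736 (-2.79 and 2.08) do not, and Pearson's r was 0.04 across probes.

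The level of the control spots differed between arrays. The Ncode_Control spots averaged 7.64 on the log2 scale on the control arrays and 7.23 on the ethanol arrays, with a spread of 0.67 between arrays, and the medians of empty and blank spots had a spread of 0.37. Between 5 and 7 of the 8 Ncode_Control spots could be used on an array. In the authors' table, which subtracts the mean of these spots, 190 of 226 zebrafish miRNAs (84.1%) were higher in ethanol, with a median difference of 0.29.

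**Figure D3:**
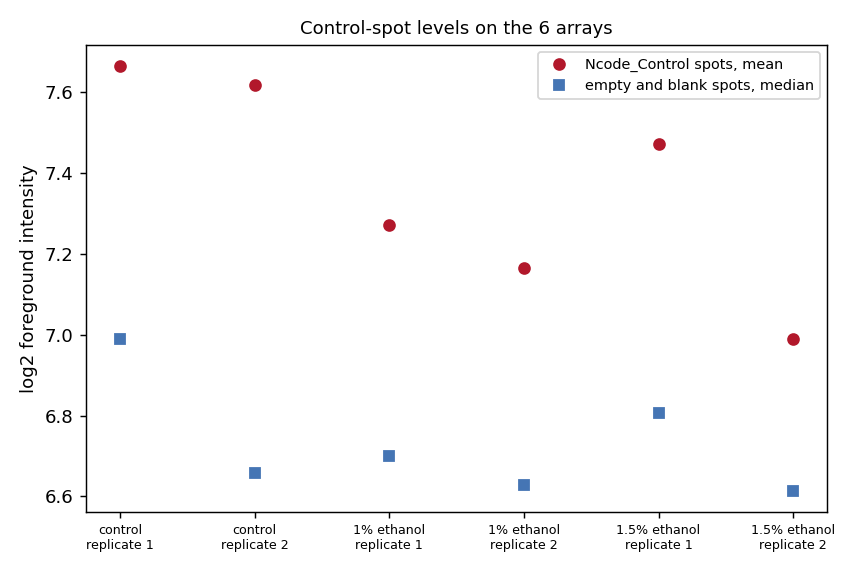
Mean log2 foreground of the Ncode_Control spots (circles) and median of the empty and blank spots (squares) on each of the 6 arrays; the axis does not start at 0. The Ncode_Control means were 7.66 and 7.62 on the control arrays and between 6.99 and 7.47 on the ethanol arrays.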

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

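In this part, the tests of array scaling, of a response growing with dose, of spot loss, of low probes on the second 1% array and of the authors' table were chosen after the result was seen, and the tests of a dim print block and of a zebrafish response among low probes of the first 1% array before.

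A signal appeared in data outside the comparisons. The rat-named probe rno-miR-382* was at 15.41 on 1% ethanol replicate 1, which is 8.32 log2 units above the higher control array (7.09). Its 4 spots read 34708 to 41625 there and at most 653 on the other arrays. The second 1% array did not show it, and its source was not tested.

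The fall of miR-128 at 1% ethanol was weighed against array scaling, a dim block and the dose order. Across 6 other scalings the difference stayed between -2.09 and -1.52, and where the call ended the SE had grown, from 0.20 to 0.38 without normalisation, 0.34 under the Ncode_Control scaling and 0.52 under the 75th percentile scaling. The 88 other probes of its print blocks had a median difference of -0.030, and the 8 of them above the empty spots on both controls had a median of -0.059 and ranged from -1.67 (let-7c) to 0.29, which argues against a block that was dim as a whole. A response that grows with dose would put 1.5% at or below 1% ethanol; the 1.5% value was 0.94 higher (0.54 after 2 SE were taken off, adjusted p = 0.291), but 0 of 2 arrays at 1% and 1 of 2 at 1.5% were above the empty spots, so graded and ungraded responses cannot be told apart. Left open are a loss of the probe's own spots on both 1% arrays and an ethanol response, graded with dose or not. Chance and differences between arrays or slides stay open too, with 2 arrays per group and slide partly confounded with group. Any of these may apply, and the loss of spots was not tested.

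On 1% ethanol replicate 1, 8 of 188 probes lay more than 2 log2 units below the median of the other arrays, among probes above the empty spots on at least 3 of those 5, beside 0 to 4 on the other arrays. Of the 8 low probes, 6 sat in 1 of 12 pairs of print blocks, out of 8 probes compared there, including miR-193b and miR-736; random placement gave a median of 2 and a 95th percentile of 3 in the fullest pair, and 0.01% of 10000 placements were as full, so spots lost in that pair of blocks are a candidate explanation for these 6. On the second 1% array 4 probes were low, 3 of them in the same pair of blocks, again with miR-193b and miR-736, and 2.58% of 10000 placements were as full. Whether a zebrafish miRNA response adds to it cannot be told apart with so few probes: 3 of 41 zebrafish probes (7.32%) and 5 of 147 probes of other species (3.40%) were low on the first array (two-sided exact Fisher p = 0.375), and 3 of 40 (7.50%) and 1 of the others (0.69%) on the second (p = 0.0328). The low values of miR-193b and miR-736 at 1% ethanol may therefore be technical, while a response of these 2 miRNAs stays open.

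In the authors' table most zebrafish miRNAs were higher in ethanol, with a median difference of 0.29. Without the constant of the Ncode_Control spots the median was -0.13, since that constant differed by 0.42 between the groups, and 27.9% of probes were then higher. Relative to the empty and blank spots, the array medians differed by -0.014 between ethanol and control (SE 0.07, 0.13 with 2 SE added), below 0.29. The median probe thus did not rise by that much over the empty spots. But 159 of 243 probes were above the empty spots on no array, so the median follows probes near background. Whether expressed miRNAs rose cannot be told from it. The shift may thus come from the few control spots used for scaling; why those spots differed was not tested.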

How the results depend on the processing

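The alternatives listed as added after the data were seen were chosen then; the others were set beforehand. "No filter" and "all 6 arrays" tested the same 243 probes as the main setting and show nothing. Counts below are miRNAs past the threshold, in the order 1% against control, 1.5% against control, 1.5% against 1%, both doses, and any difference; the main counts were 1, 0, 0, 1 and 1, and the cause of a change was not tested unless given.

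With median scaling the last 2 counts were 0 and 0, as with cyclic loess and with the replicate block. Without normalisation the counts were 0, 0, 2, 0 and 0, as in the authors' table and under the Ncode_Control scaling, with or without background subtraction. The median over spots gave 0 throughout. Slide as a fixed block gave 3, 2, 4, 2 and 6, with 1 residual degree of freedom, and a correlation between doses of 0.18. In that fit miR-128, miR-193b and miR-736 had the same SE of 0.43, so its calls rest on a shared spread. The 75th percentile scaling gave 2, 2, 3, 0 and 3, and scaling to empty and blank spots gave 2 at 1% (let-7c and miR-128). Keeping ignored spots gave 0 for any difference. Limited to 41 probes above the empty spots on both arrays of a group, any difference gave 0 and the correlation was -0.13 (-0.14 without background subtraction). Limited to the 28 probes above on all 6 arrays, which leave out miR-128, the counts were 0 and the correlation was 0.21. With the 84 probes above on at least 1 array, any difference gave 0, also with random slide or replicate effects; with the replicate block or slide as a fixed block all counts were 0; with position on the slide they were 4, 0, 4, 2 and 5.

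With each array left out, where the lone array of a group is assumed to vary like the others, the counts ranged over 0 to 3, 0 to 0, 0 to 3, 0 to 0 and 0 to 1, the correlation from -0.084 to 0.37, and the lists past camera from 0 to 1. Lists past camera stayed at 0 in all 32 alternatives that kept every array. The count at 1% kept within 1.5 times its value in 20 of 32 such alternatives, at 1.5% in 30, between doses in 25, for both doses in 17 of 31, for any difference in 12 of 31, and the correlation stayed within its spread in 28 of 33, and was 0.25 with the probe of miR-736 left out. Several of these alternatives leave the fold changes as they were, so their agreement in the correlation was fixed in advance. miR-128 at 1% ethanol stayed below 0 in all 37 alternatives, -2.41 to -1.52, past the threshold in 26, some of which repeat the same fit. At 1.5% it ran from -1.20 to -0.31 and between doses from 0.53 to 1.25, never past. Of 7928 values of named miRNAs not past the threshold, 633 had the other sign, still not past, 30 passed in the same direction and 0 reversed; of the 37 values of miR-128 at 1% ethanol, 11 lost the call. Scaling moved the median of all probes: at 1% and 1.5% ethanol it was 0.27 and 0.32 in the authors' table, 0.27 and 0.44 under the Ncode_Control scaling, 0.35 and -0.02 at the 75th percentile, and -0.21 and 0.03 relative to empty and blank spots. With 159 of 243 probes above the empty spots on no array, signal over background limits what could be seen for most miRNAs. The alternative with only the groups compared gives no value for both doses, any difference or lists.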

Other observations

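The tests of probes for other species and the ranges over the spots of a probe were all chosen after the data were seen.

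Probes named for other species numbered 835, and 16.9% to 22.99% of them were above the empty spots per array. Tested in the same way with limma, 1 passed at 1% ethanol against control, hsa-miR-656 (adjusted p = 0.0401), beside 37 at an unadjusted p under 0.05, where 41.75 are expected by chance. At 1.5% ethanol 0 passed (33 at an unadjusted p under 0.05), and between the doses 1, again hsa-miR-656 (adjusted p = 0.0116).

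Spots of the same probe differed on some arrays. Among zebrafish probes with a spot above the empty spots, 9.57% to 28.4% per array had spots more than 4-fold apart. miR-203a ranged from 536 to 26639 over its 4 spots on control replicate 1, and from 16874 to 18806 on 1.5% ethanol replicate 2. ZF_miR_20 read 90 to 115 on 1% ethanol replicate 1 and 1797 to 2363 on 1% ethanol replicate 2. miR-128 read 559 to 690 and 362 to 414 on the control arrays, 92 to 156 and 102 to 156 on the 1% arrays, and 97 to 551 and 154 to 277 on the 1.5% arrays.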
